A study of Drosophila subpalustris with 2 samples.

How the data were processed

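Polyadenylated RNA of whole adult Drosophila subpalustris was sequenced in 2 libraries. Each library came from a separate pool of 10 to 20 adults of both sexes, described by the submitters as biological replicates. Libraries were made from 1 µg of RNA with a directional kit, so each read keeps the strand of its transcript. The ratio of males to females in each pool is not given in the sources used here.

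Reads were handled with fastp and aligned and counted with STAR 2.7.11b, per the submitters' processing notes. The fastp version, the trimming and alignment settings, and whether reads were single or paired are not given in the sources used here. The gene models come from a draft assembly of the species. They were built with BRAKER 3.0.6, per the submitters' series description, which names these RNA reads as evidence for the annotation. A model that has counts is therefore not an independent test of that annotation.

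The authors deposited 1 table of raw counts per library, with 3 count columns for each of 17716 gene models. The columns hold counts on either strand, on one strand and on the opposite strand, read from the layout of a STAR gene count table because the tables have no header. The first 4 rows of each table are totals of unmapped, multimapping, unassigned and ambiguous reads, given for each column. They were kept out of library sizes and tests, and their shares are reported as measurements. Multimapping reads are assigned to no model in this layout, so models with near-identical copies can be undercounted.

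The last count column was taken as the sense count, because the kit marks strand and this column held the larger sum in both libraries. Sense counts summed to 26141490 in replicate 1 and 25544996 in replicate 2. Expression as CPM (counts per 1e6 assigned counts) was computed on these sums. A count of 0 allows up to 3 counts, which is 0.115 CPM in replicate 1 and 0.117 CPM in replicate 2. Intervals and this limit cover counting error only, because reads without molecular identifiers are not independent molecules.

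The series holds 1 group, so no comparison between conditions exists and none was made. Detection, concentration of the counts and the difference between the libraries were described. A model was called detected at 10 or more sense counts in each library. The Pearson correlation used log2(CPM + 1), over models with 10 or more counts in at least 1 library, with a 95% interval from 1000 resamples of the models. The dispersion was estimated on these models with estimateDisp of edgeR 4.0.16 in R 4.3.3, with an intercept only and trimmed mean of M-values (TMM) scaling, which leaves 1 residual degree of freedom per model. Ratios of replicate 2 to replicate 1 used TMM-scaled CPM, and models with a mean CPM of 10 or more were counted at 2-fold. A two-sided exact binomial test per model, with Benjamini-Hochberg adjustment at 0.05, compared the 2 libraries over models with 10 or more counts in sum. It asks whether the libraries differ by more than sampling and does not compare conditions. Python 3.11.15, scipy 1.17.1 and pandas 2.3.3 were used.

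The procedures were tested on simulated data with the TMM-scaled library sizes and the expression levels of replicates 1 and 2. Simulated dispersions of 0.01, 0.1 and 0.3 came back as 0.0099, 0.098 and 0.295, over 12900, 12878 and 12905 models. Each simulation gave all models the same dispersion and the same level in both libraries. Recovery therefore does not cover dispersions that vary between models, or ratios that change with expression level. The exact binomial test ran on 13227 simulated models whose counts held sampling noise only. Changed models were drawn from those with an expected sum of 50 or more counts. The test called 80 of 100 models changed 1.5-fold, 100 of 100 models changed 3-fold and 5 of 13027 unchanged models. These rates do not cover changed models with fewer counts, or libraries that differ by more than sampling.

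Models were named by a rule set before the data were examined. The rule took the 2 models of highest mean CPM and, among models with a mean CPM of 10 or more, the 2 with the largest ratio in each direction. The deposited tables give locus identifiers only and do not pair them with gene names, and no genome or annotation was used here. The 16 lists of Drosophila melanogaster genes fixed in advance were therefore not tested, and positions, lengths and base composition of the models were not analysed here. The alternatives, also fixed in advance, were other count columns, count and CPM minimums, pseudocounts, library totals or DESeq2 1.42.0 size factors in place of TMM, a DESeq2 dispersion estimate, thinned or halved counts, and each library alone.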

Results

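RNA of whole Drosophila subpalustris adults was sequenced to provide evidence for annotating a draft genome of this fly. The data comprised 2 libraries from separate mixed-sex pools, which formed 1 group. STAR counted 42382083 reads in replicate 1 and 43438716 in replicate 2. Whether these are single reads or read pairs is not given in the sources used here. Of these, 26141490 and 25544996 were assigned to the sense strand of a gene model. The assigned share was 61.7% in replicate 1 (95% exact binomial interval 61.67 to 61.70) and 58.8% in replicate 2 (58.79 to 58.82). At this depth, 10 counts correspond to 0.383 CPM in replicate 1 and 0.391 CPM in replicate 2.

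Of all reads, 24.6% in replicate 1 and 30.7% in replicate 2 aligned to the sense strand of no gene model's exons. This class includes antisense reads in models. Reads on neither strand of a model's exons made up 24.2% and 30.3%. The count layout goes by annotated exons, so both classes can include reads from introns or from transcript ends that the models lack. Unmapped reads made up 11.3% and 7.15%, and multimapping reads 2.00% and 3.12%, respectively. Ambiguous reads, which overlap more than one model on the same strand, made up 0.377% and 0.222%. The exact counting intervals of each of these shares did not overlap between the libraries, but no spread between further replicates can be set beside them.

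**Figure D1:**
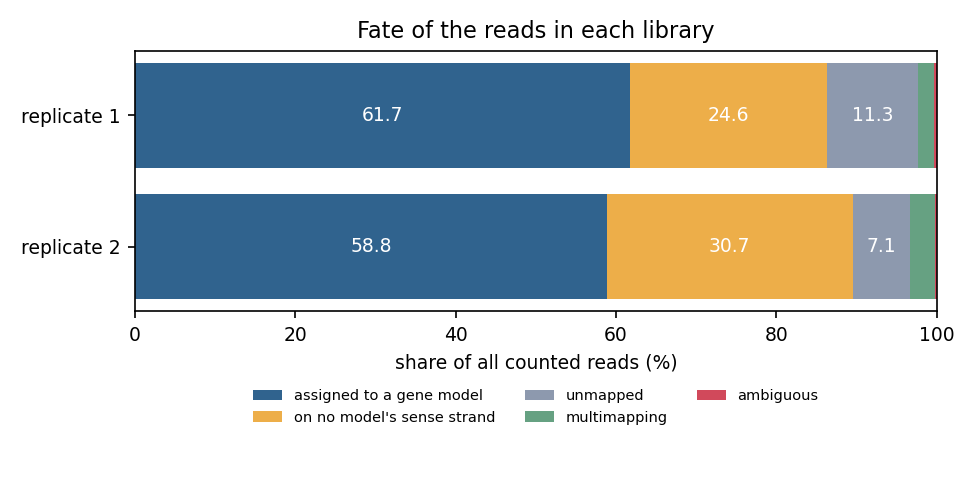
Stacked horizontal bars give the share of all counted reads (%) by fate in replicate 1 and replicate 2, with shares above 5% printed. Reads on the sense strand of no model's exons took 24.6% in replicate 1 and 30.7% in replicate 2.

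The reads in gene models were almost entirely on the annotated strand. The sense share of strand-specific counts was 99.16% ± 0.01 (SD, n = 2), with 219012 antisense counts in replicate 1 and 217820 in replicate 2. Antisense counts made up 0.831% in replicate 1 and 0.845% in replicate 2. They can include sense reads of an overlapping model on the opposite strand. The sense column was chosen for its larger sum, and the submitters name these reads as evidence for the models. The sense share is therefore not an independent check of the strand given by the models.

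The first question the design poses is how many of the predicted genes have RNA in adults. Of 17716 gene models, 12294 (69.4%) had at least 10 sense counts in both libraries, and 11360 (64.1%) reached 1 CPM in both. Replicate 1 alone reached 10 counts for 515 further models, and replicate 2 alone for 148. Neither library reached 10 counts for 4759 models (26.9%), of which 2315 had no sense count at all, which allows up to 3 counts per library. The number detected was 12626 ± 260 per library (SD, n = 2). Thinning replicate 1 to the depth of replicate 2 gave 12288 models detected in both, so the small difference in total counts did not set this number. Thinning leaves in place the larger share of counts that the top models took in replicate 2. Depth for the other models therefore stays open as a source of the 515 against 148.

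Counts were concentrated in few models. CPM was not corrected for model length, so the most abundant models here are those with the most counts. The 177 models with a mean CPM of 1000 or more, 0.999% of all models, held 42.3% of the counts in replicate 1 and 54.1% in replicate 2. The 100 most abundant models held 37.3% ± 6.2 of the counts (SD, n = 2), and the 10 most abundant held 11.5% ± 0.2 (SD, n = 2). The models needed to reach 50% of the counts numbered 268 in replicate 1 and 142 in replicate 2. The most abundant model was ACLKA7_009625, with 22445 CPM in replicate 1 and 31328 CPM in replicate 2, a mean of 26887 ± 6282 (SD, n = 2). ACLKA7_003910 followed with 28396 CPM in replicate 1 and 19494 CPM in replicate 2, a mean of 23945 ± 6294 (SD, n = 2). The order of these 2 models thus differed between the libraries, and their means differed by less than the spread between replicates. Their antisense counts were at most 342 in any library. The tables give no gene name for either model.

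The second question is how far the replicates differ. Expression levels were correlated across gene models, with a Pearson r of 0.908 on log2(CPM + 1) (bootstrap interval 0.904 to 0.911) and a Spearman rho of 0.888 (0.884 to 0.892) over 12957 models. Gene models are not independent replicates, and no p-value was attached to these correlations. The common dispersion estimated by edgeR was 0.256, a coefficient of variation between replicates of 50.6%. By the exact binomial test, 10196 of 13241 models (77.0%) differed between the libraries by more than sampling at a Benjamini-Hochberg threshold of 0.05. With the TMM-scaled library sizes used in this test, 5026 of these were higher in replicate 2 and 5170 higher in replicate 1. TMM centres the ratios, so a near-even split depends on the scaling, as for the 2-fold counts below. The test compares these libraries only, and says nothing of a condition.

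**Figure D2:**
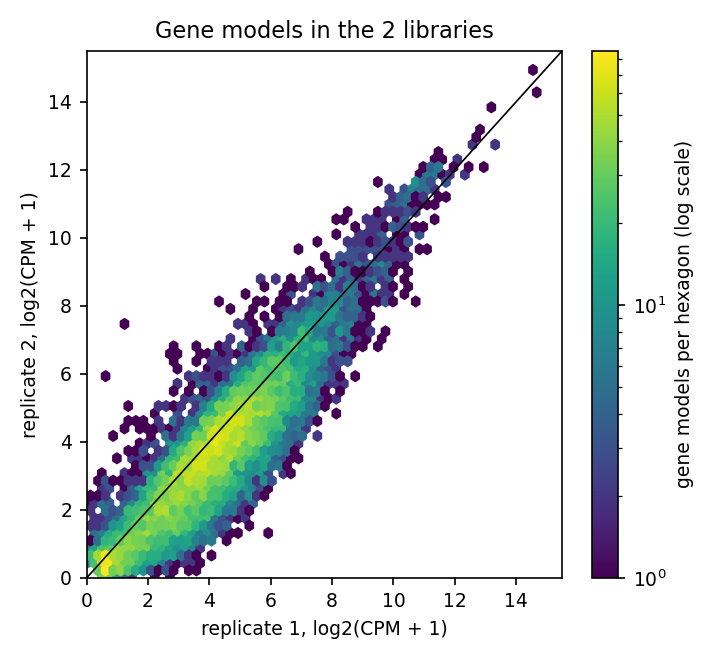
Each hexagon shows how many gene models have a given log2(CPM + 1) in replicate 1 (horizontal axis) and replicate 2 (vertical axis), on a log colour scale, for the 12957 models with 10 or more counts in at least 1 library. The line marks equal CPM, and the Pearson r of the plotted values is 0.908.

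The difference between the libraries changed with expression level. The most abundant models, with a mean CPM of 1000 or more, had a median log2 ratio of replicate 2 to replicate 1 of 1.08 with TMM scaling (quartiles 0.65 to 1.33), and 98 of these 177 models were at least 2-fold higher in replicate 2 against 1 in replicate 1. Their median was 0.56 when library totals set the scale, where 24 models were at least 2-fold higher in replicate 2 and 5 in replicate 1. Models of 100 to 1000 CPM had a median of 0.32 with TMM, and this sign flipped with library totals (-0.20). The medians were 0.00 for models of 10 to 100 CPM and -0.19 for models of 1 to 10 CPM with TMM, and -0.52 and -0.70 with library totals. TMM moved all log2 ratios by 0.52 against library totals, so only the differences between expression classes are independent of the scaling.

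**Figure D3:**
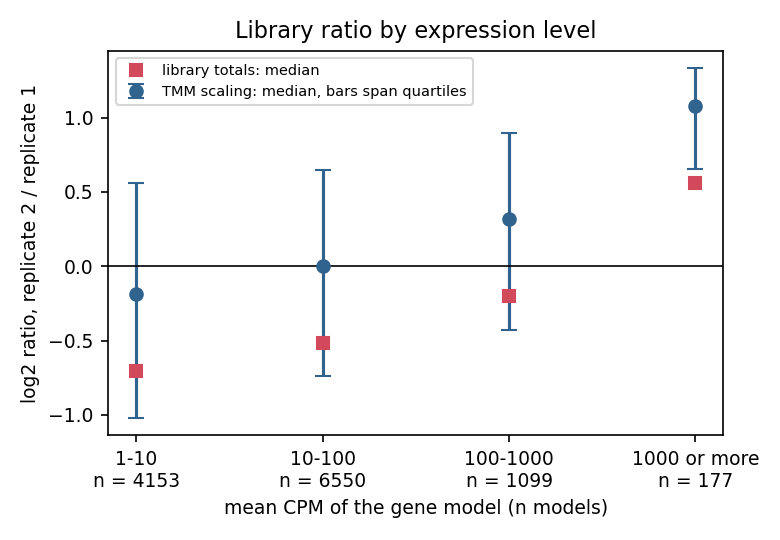
The median log2 ratio of replicate 2 to replicate 1 is plotted for 4153, 6550, 1099 and 177 gene models in classes of rising mean CPM. Circles with quartile bars use TMM scaling and squares use library totals. The highest class lies at 1.08 and 0.56, above the other classes under both scalings.

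Among 7826 models with a mean CPM of 10 or more, 2514 (32.1%) differed at least 2-fold between the libraries. With TMM, 1198 were higher in replicate 2 and 1316 higher in replicate 1. With library totals the split was 386 against 2412, and with DESeq2 size factors it was 1234 against 1286. Counts simulated with sampling noise alone gave 0 such models. The median absolute log2 ratio was 0.69, against 0.04 from sampling noise. In models of 1 to 10 CPM it was 0.77 against 0.13 from sampling noise, and in models of 100 to 1000 CPM 0.67 against 0.02. In models of 1000 CPM or more it was 1.08 against 0.007, which includes the shift of that class towards replicate 2 with TMM.

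The largest differences towards replicate 2 were in 2 models with neighbouring identifiers. ACLKA7_012625 had 31 counts in replicate 1 and 4283 in replicate 2, a log2 ratio of 7.66 (95% counting interval 7.15 to 8.22). ACLKA7_012627 had 12 and 1629 counts, a log2 ratio of 7.64 (6.83 to 8.59). Towards replicate 1, ACLKA7_000181 had 1560 counts in replicate 1 and 40 in replicate 2, a log2 ratio of -4.73 (-5.23 to -4.28). ACLKA7_006773 had 799 and 35 counts, a log2 ratio of -3.96 (-4.49 to -3.47). These models were chosen for their ratio, so the values overstate what a new pair of libraries would show. With 1 library on each side, the ratios have no replicate check.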

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

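The tests of unshared counts, of strand marking and of the replicate spread were chosen only after the result was seen.

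The antisense counts, described above mainly by their sum, held a signal in 246 gene models (1.39% of all). In these, antisense counts exceeded sense counts and reached 10 in both libraries. They carried 41.0% of all antisense counts in replicate 1 and 50.1% in replicate 2. They fell into groups by how many of their strand-specific counts were missing from the unstranded column, where a read shared by 2 models on opposite strands is ambiguous. In 26 models at least 50% was missing in both libraries. Of these, 24 had a neighbour by locus tag that lost a matching number of counts, within 10% in both libraries. Reads of an overlapping neighbour on the opposite strand are a candidate explanation there. These models were chosen by that loss, which arises where models overlap, so the overlap itself was given by the choice. The match shows only that the overlapping model mostly had an adjacent tag. In 178 of the 246 (72.4%) less than 5% was missing in both libraries, which argues against annotated overlapping neighbours as the whole source. Their median antisense share was 90.2% in one library and 91.6% in the other. Each model was then given the library-wide antisense share (0.831% and 0.845%). The number of models expected to meet the rule of the 246, among all 17716, was 5.66e-32. This argues against incomplete strand marking at one rate per library, although so small an expectation follows from that rule. Any model that met the rule would have given the same result. Of the 178, 41 had at least 100 antisense counts in both libraries and 21 had no sense count in either. Models drawn on the wrong strand and transcripts missing from the annotation stay open and were not tested. The other 42 models lay between these groups. No biological explanation was tested, since the design has 1 group.

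The reads on the sense strand of no gene model's exons (24.6% in replicate 1 and 30.7% in replicate 2) are described above by their share alone. Apart from the antisense reads in models, they were not analysed further.

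The replicates differed widely in single models. The SD of the log2 ratio was 1.05 over models with a mean CPM of 10 or more, against 0.08 in counts simulated with sampling noise and one scaling factor per library, but that simulation leaves out variation from library preparation. Technical and biological sources of the spread cannot be told apart with 1 library per pool. Bias by transcript length or base composition was not tested, because neither property was analysed here. The sex ratio, age and physiological state of the pools are biological differences that stay open and untested, because the identifiers carry no names.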

How the results depend on the processing

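Of the 42 alternatives for the main results, 29 left the value within the replicate spread, the resampling interval or 1.5 times the count, and 13 did not. Some of the 29 could not have moved. With 2 libraries, either one alone lies within the SD of their mean sense share. Settings that only raise the number of detected models cannot reach 1.5 times it, which exceeds all 17716 models. The 29 are therefore not a measure of robustness. The sense share was 99.20% over models with 10 or more unstranded counts in both libraries and 98.70% without the 100 most abundant models. The share of the 100 most abundant models was 22.4% of all input reads. The Pearson r was 0.913 with unstranded counts and 0.902 with a pseudocount of 0.1 CPM. It was 0.948 with no low-count filter and 0.826 for models with a mean CPM of 10 or more, so its size depended on which models were included. The dispersion was 0.244 with unstranded counts, 0.320 with library totals, 0.229 for models with a mean CPM of 10 or more and 0.115 as the median of DESeq2's estimates per model, which is a different summary. Models differing at least 2-fold numbered 4106 at a mean CPM of 1 or more and 448 at 100 or more, as fewer models enter. Detected models ranged from 10513 (50 counts) to 14104 (1 count). Models beyond sampling noise ranged from 9044 (counts halved) to 10499 (library totals). Without replicate 1, 12442 models were detected and the 100 most abundant held 42.0%; without replicate 2, 12809 and 33.5%. Measures of the difference need both libraries. The alternatives for gene lists were not run, because the identifiers carry no names. Counts below 10 limit what can be said of the 4759 undetected models.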

Other observations

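The tests of the last block, of neighbouring ratios, of clusters of large ratios, of the block medians, of runs of neighbouring models and of block 6 were chosen only after the result was seen.

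Gene models in both tables are listed in 7 blocks, each with rising locus-tag numbers, of 3160, 2959, 3072, 3928, 97, 3038 and 1462 models. The first 6 blocks had similar detection, from 69.5% to 82.5% of models with 10 or more counts in both libraries. In the last block, 48 of 1462 models (3.28%) were detected, and 900 (61.6%) had no sense count in either library. This block held 8.25% of the models of the annotation, 29.3% of the undetected models, and 0.0359% and 0.0275% of the counts in replicates 1 and 2. Without it, 12246 of 16254 models (75.3%) were detected.

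Technical explanations were weighed for the low detection in the last block. Models placed on the wrong strand would carry antisense counts if their reads aligned uniquely. Only 11 models of the block (0.752%) had 10 or more in both libraries, which argues against this explanation for such models. Antisense reads that multimap are counted for no model, so the test cannot decide for models with near-identical copies. The test was first run on the 1771 models of highest locus tag (12.3% with 10 or more antisense counts) and decided nothing. Of those models 75.6% were detected, so that set did not hold the pattern, and the blocks were defined after that result. Reads shared with near-identical copies, which are counted for no model, cannot be told apart from absent expression. All multimapping reads of a library amount to 609 per undetected model of this block in replicate 1 and 973 in replicate 2. They can come from any block, so these are upper limits. They are 1.25 and 3.02 times the median count of detected models elsewhere. A mean is here set beside a median of unequal counts, so the ratios leave this explanation open and do not favour it. Locating these reads needs the alignments, which were not used here. No biological explanation was tested.

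A hypothesis was that the locus tags follow the order along the assembly. Of 43 models with at least 100 shared counts in both libraries, 36 (83.7%) had a next or previous tag with a matching shared count, within 10% in both, against at most 2 in 1000 shuffled orders. This is consistent with neighbouring tags being neighbours on the assembly, at least where models overlap.

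Neighbouring models also had similar ratios between the replicates. Over 3069 pairs of adjacent tags without shared counts, the Pearson r of the log2 ratio across pairs of models was 0.171 (Spearman 0.118). The permutation test used the mean product of the centred ratios within pairs. Ratios were shuffled over all models with a mean CPM of 10 or more. Its one-sided permutation p was 1e-05 (adjusted 2e-05 over 5 distances), the smallest that 100000 permutations can give. The Pearson r was 0.11 at a distance of 2 tags, 0.05 at 5, 0.02 at 10 and -0.01 at 50. The effect was small, since 54.1% of adjacent pairs deviated in the same direction. Models at least 8-fold higher in replicate 2 were clustered: 26 of 47 lay within 5 tags of another, against 1.49 on average in random draws (one-sided permutation p = 1e-05, adjusted 2e-05). Of 22 models at least 8-fold higher in replicate 1, 2 did so (permutation p = 0.15, adjusted 0.20). With library totals the numbers were 7 of 22 towards replicate 2 (permutation p = 1e-05, adjusted 2e-05) and 6 of 90 towards replicate 1 (permutation p = 0.51, adjusted 0.51), so which direction holds more such models depends on the scaling. The difference between the directions was not tested. Tandem gene families, and single genes split into several models, may both give such clusters, and neither was tested. The ratios of neighbours and of clusters were not adjusted for expression level, with which the ratios also changed.

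The median ratio also varied between blocks. Over the 5 blocks with more than 1000 models of a mean CPM of 10 or more, block medians of the log2 ratio spanned 0.222, from -0.07 in block 6 to 0.15 in block 2, with a permutation p of 1e-05, the smallest the permutations can give. With library totals each block median lay below 0 (-0.59 in block 6, -0.36 in block 2), with the same span. That p treats neighbouring models as independent, so it is too small. The span of these 5 blocks was not tested with neighbours kept together. Block 5, with 59 such models, had a median of -0.62 with TMM and -1.14 with library totals, and 24 of its models were at least 2-fold higher in replicate 1 against 5 in replicate 2. After subtracting the median of models of similar mean CPM its median was -0.73 (permutation p = 2e-05, too small for the same reason). Runs of 59 neighbouring models by locus tag keep that likeness: of 7651 runs without a model of this block, 0 lay as far from the median of all models, and the lowest median was -0.60. Of all 7768 runs, 3 (0.0386%) lay as far, each holding models of this block. This argues against expression level as the whole cause, although the runs overlap and the block was picked for its low median. With TMM scaling, block 6 held 1 of the 47 models at least 8-fold higher in replicate 2. That was 0.0783% of its 1277 models with a mean CPM of 10 or more, against 0.702% of such models elsewhere. The adjusted p was 0.027 over 6 blocks (two-sided Fisher exact test). With each cluster of tags counted once, the numbers were 1 against 30 and the unadjusted exact p was 0.049, so this difference was not established. If blocks are chromosomes, a difference in the sex ratio of the pools is a candidate explanation for such shifts, which was not tested because the sequences behind the blocks were not analysed here.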
